A study of Homo sapiens with 9 samples.

How the data were processed

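Gene expression was measured in human mesenchymal stem cells from bone marrow, the precursors of bone, cartilage and fat cells of the marrow stroma. Per the labels, the cells carried a scramble short hairpin RNA (shRNA), an shRNA against the histone demethylase KDM4B or an shRNA against the histone demethylase KDM6B. They were treated with bone morphogenetic proteins (BMP4/7) for 0, 4 or 24 h. Each of the 3 arms had 1 Affymetrix array at each of the 3 times, 9 arrays in all, so that no combination of arm and time had a replicate. Nothing in the labels says that the arrays came from separate cultures or donors. The p-values therefore measure only the spread between these samples, which may be technical.

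The deposited values were intensity values on a linear scale, 1 signal for each of 54675 probe sets per array, made with the MAS5 algorithm per the submitters' processing notes. The version of MAS5 was not given in the sources used here. The trimmed mean of the deposited signals was 500.1 on every array, so the arrays had been scaled to a common mean before deposit. MAS5 works on each array alone and makes no other adjustment between arrays, so a difference in background or in labelling can remain in the values. No further normalization was applied here. All 9 sample columns were used.

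Genes were named through the platform's annotation table. It listed 42898 probe sets, of which 41097 had 1 gene symbol and 1801 had several. The other 11777 probe sets were not listed and are unnamed here, which does not mean that they lack a gene. Probe sets with several symbols were not used. By Entrez ID, 41043 probe sets matched the gene reference and 0 symbols needed updating. Of 19740 genes with a usable probe set, each was represented by the probe set with the highest mean log2 signal. No coordinates were used here.

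Signals were analysed as log2(signal + 23.04), where the added constant was the 25th percentile of all deposited signals. A fold change on this scale understates the change of dim genes. Genes were kept if at least 3 of the 9 arrays exceeded 81.86, the 50th percentile of all signals, which left 13246 genes. Models were fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a variance trend, 2-sided, and Benjamini-Hochberg adjustment over all genes tested at 0.05. An additive model of arm and time gave 6 comparisons, 3 between arms over the 3 times and 3 between times over the 3 arms. It had 4 residual degrees of freedom and 8.56 prior degrees of freedom. The spread in this model is how far a difference varied across the times or arms, so an interaction counts as spread. A model with arm, time and the product of arm and treatment (4 and 24 h together against 0 h) gave 2 comparisons of the BMP response between arms. It had 2 residual and 7.63 prior degrees of freedom. Each 0 h array is fitted exactly there, so the spread comes from the 4 and 24 h arrays and the 0 h baseline of 1 array per arm is assumed to vary like them. Differences at a single time had 1 array per arm and were given no test. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.189 in the additive model and 0.381 in the interaction model.

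In all, 24 gene lists were fixed. They covered histone demethylases, BMP feedback targets, DLX genes, HOX genes, osteogenic transcription factors, bone matrix and mineralisation, adipogenic genes, chondrogenic genes, TGF-beta and contractile genes, Notch targets, Wnt targets and the cell cycle. They further covered p53 targets and cell cycle inhibitors, the interferon response, NF-kB and inflammatory genes, immediate early genes, cholesterol synthesis, endoplasmic reticulum (ER) and amino acid stress, hypoxia and glycolysis, and polycomb components. Markers of stromal, blood, endothelial and muscle cells completed them. The DLX and HOX lists follow what is known of the published study of these samples and are not independent evidence. Each list was tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, and adjusted over 192 tests. Of the 192 tests, camera called 38 at the preset correlation and 2 with an estimated correlation, and fry called 16. Fry called 0 lists between the 2 shRNA arms and 0 in each of the 2 comparisons of the BMP response. Both calls with an estimated correlation were for the BMP feedback targets, at 4 h and at 24 h against 0 h. For differences at a single time, a list's median was placed among 10000 random lists of the same size matched on mean expression.

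The genes named in the text follow a rule. It takes KDM4B and KDM6B always. For each comparison it takes the 10 largest rises and the 10 largest falls past an adjusted p of 0.05 with the same sign at every time or in every arm. Where fewer passed, list members fill the places. Up to 4 tested members of each list with the largest absolute fold change are added. XIST and Y-linked genes were left out. Genes outside this rule are marked as chosen after their values were seen. DLX2 and DLX5 in the comparisons of arms were also chosen after their values were seen. The groups, models, lists, naming rule and alternatives of scaling, added constant, filter, probe set choice, variance model and arrays left out were fixed before the data were examined.

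The models were tested on simulated data with the real arrays' levels and spread, in which 200 of 13246 genes were changed. Noise was drawn independently for each gene and array, so differences shared by the genes of an array were left out. For KDM4B shRNA against scramble, 69% of genes changed by 1 and 94% of genes changed by 2 on the log2 scale were recovered, with 12 false calls among 175. For the KDM6B-labelled arm against scramble, the shares were 65% and 86%, with 16 false calls among 167. For the BMP response of the KDM4B arm against scramble, they were 23% and 63%, with 13 false calls among 99. For that of the KDM6B-labelled arm, they were 11% and 51%, with 6 false calls among 68. Because both comparisons with scramble use the same scramble arrays, 100 simulated pairs of unchanged arms gave the correlation and overlap to set beside the observed ones. The overlap of simulated lists as long as the real ones was added after seeing the data.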

Results

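The messenger RNA of human bone marrow mesenchymal stem cells was profiled on 9 Affymetrix arrays to find genes regulated by 2 histone demethylases under BMP, in a study of osteogenic differentiation. Whether the cells moved toward bone was not tested here. KDM4B removes methyl groups from histone H3 lysine 9, and KDM6B removes them from histone H3 lysine 27. A scramble shRNA arm, a KDM4B shRNA arm and a KDM6B shRNA arm were each measured after 0, 4 and 24 h of BMP4/7, with 1 array per arm and time. Errors below are standard errors of log2 fold changes from the fit over 9 arrays, so that n = 3 arrays per arm or per time in each comparison. Correlations of log2 signals across genes ranged from 0.952 to 0.971 between arrays of the same arm, from 0.95 to 0.967 between arrays of the same time in different arms, and from 0.938 to 0.961 between arrays of different arm and time, with medians of 0.96, 0.962 and 0.953. The median signal of an array was 71.5 to 73.3 in the scramble arm and 82.4 to 92.4 in the shRNA arms. RNAs spiked into the hybridisation were 1.82-fold brighter in the KDM4B arm than in the scramble arm and 1.44-fold brighter in the KDM6B arm. The ratio of 3' to 5' signal of ACTB, a sign of RNA integrity, was higher in both shRNA arms than in scramble at every time. It was 7.04 in the KDM4B arm and 6.75 in the KDM6B arm against 6.42 at 0 h, 6.27 and 6.21 against 5.03 at 4 h, and 6.2 and 6.28 against 5.55 at 24 h. The ratio of GAPDH ranged from 1.06 to 1.21. In every arm the ACTB ratio and the spiked RNAs were also lower at 4 and 24 h than at 0 h.

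The targeted genes were examined first, since they check the labels. KDM4B fell in the KDM4B arm by 0.77 ± 0.13 on the log2 scale (adjusted p = 0.00172), with signals of 1606, 1825 and 1820 at 0, 4 and 24 h against 3245, 3191 and 2601 in the scramble arm. In the KDM6B arm KDM4B stood at -0.30 ± 0.13 against scramble (adjusted p = 0.178), and the difference of -0.47 between the shRNA arms did not pass (adjusted p = 0.0823). KDM6B did not pass in its own arm, where it stood at 0.26 ± 0.18 (adjusted p = 0.45), with signals of 467, 391 and 529 against 416, 292 and 446. The 5 probe sets of KDM6B ranged from -1.06 to 0.26 in that arm and 3 of them were lower, with a mean of -0.23. KDM6B stood at 0.46 ± 0.18 in the KDM4B arm (adjusted p = 0.131). The label of the KDM6B arm is thus not borne out by its target, and the arm is called KDM6B-labelled below. Of the 7 probe sets of KDM4B above the signal filter, 5 were lower in the KDM4B arm. The mean over these 7 was -0.45. With the mean over all 8 probe sets, 1 of them above the filter in 1 array only, KDM4B stood at -0.28 and did not pass (adjusted p = 0.339), nor did it without a variance trend (adjusted p = 0.0532).

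**Figure D1:**
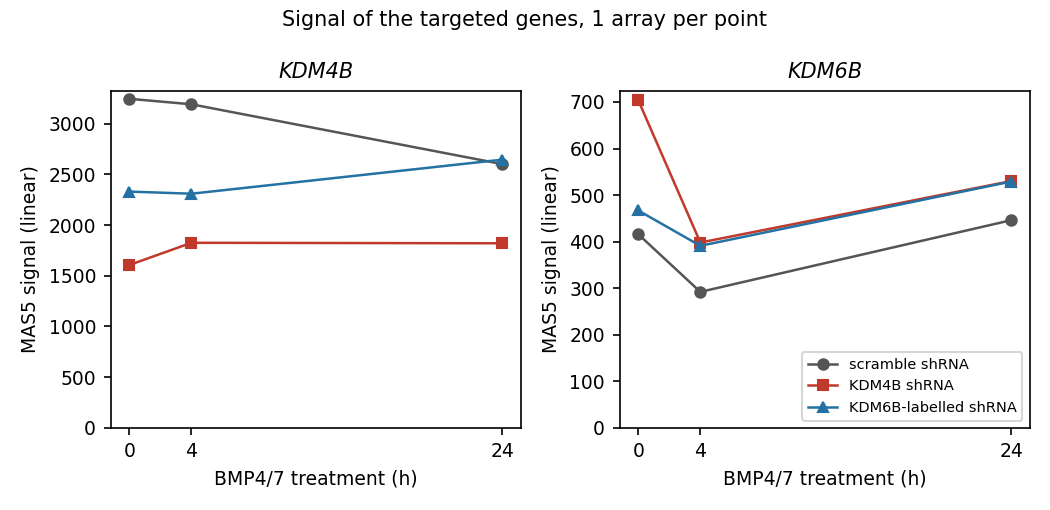
Deposited linear signal of KDM4B and KDM6B (vertical axes, MAS5 signal units) against hours of BMP4/7 (horizontal axes), with 1 array per point and 1 line per arm. KDM4B lay between 1606 and 1825 in the KDM4B arm and between 2601 and 3245 in the scramble arm, while KDM6B lay between 391 and 529 in the KDM6B-labelled arm and between 292 and 446 in the scramble arm.

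The response to BMP was first taken at 4 h against 0 h over the 3 arms. The inhibitors of differentiation ID1 and ID3, direct targets of BMP signalling, rose by 4.85 ± 0.15 and 3.45 ± 0.09 on the log2 scale (adjusted p = 1.17e-09 and 2.48e-10). The homeobox gene DLX2 rose by 4.02 ± 0.14, and the secreted BMP antagonist NOG and the inhibitory signal transducer SMAD6 rose by 2.85 ± 0.21 and 2.53 ± 0.17. The ubiquitin ligase FBXO32 fell by 1.69 ± 0.14. TNFRSF11B, the decoy receptor osteoprotegerin that restrains bone resorption, fell by 0.88 ± 0.09. In all, 167 genes rose and 111 fell of 13246 tested, while the ACTB 3' to 5' ratio and the spiked RNAs were lower at 4 h in every arm.

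Of 16 BMP feedback targets tested, 11 rose at 4 h and 0 fell, and 11 rose adjusted over the list alone. Examples are ID1, ID3, SMAD6 and ATOH8, a transcription factor, at 3.14 ± 0.23, and the list was called with an estimated correlation too (adjusted p = 0.0463). All 5 DLX genes tested rose, from 1.23 for DLX6, chosen after its value was seen, to 4.02 for DLX2, and all 5 passed adjusted over the list alone (camera adjusted p = 2.76e-13, adjusted p = 0.158 with an estimated correlation). Of 19 HOX genes, HOXB6 rose by 1.24 and HOXC9 by 1.05, 17 did not pass, and the count was also 2 adjusted over the list alone. Only 1 of the 2 probe sets of HOXB6 rose. Because the DLX and HOX lists follow the published study of these samples, their counts are not independent evidence. Of 13 osteogenic transcription factors, DLX3 rose by 2.27, DLX5 by 2.2, CBFB, the partner of RUNX2, by 1.67 and MSX1 by 1.01, and 9 did not pass. The count was also 4 adjusted over the list alone, and camera's call (adjusted p = 0.00341) was lost, at an adjusted p = 0.43 with an estimated correlation. Of 7 Notch targets, the repressor HES1 rose by 2.2 and the ligand JAG1 by 0.65, with 3 adjusted over the list alone (camera adjusted p = 0.00906, adjusted p = 0.485 with an estimated correlation). Of 21 NF-kB and inflammatory genes, the monocyte attractant CCL2 fell by 1.11 ± 0.23 and 20 did not pass, also adjusted over the list alone, with a list median of -0.22. Camera called that list (adjusted p = 0.00922, adjusted p = 0.841 with an estimated correlation), but its median was 0.06, on the other side of 0, without the KDM4B array at 0 h. CCL2 stood at -0.73 without that array or without the KDM4B array at 4 h and then did not pass.

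Of the other lists at 4 h, the adipogenic genes ZNF423 and CEBPA rose by 1.07 and 1.7 of 10 tested, with 2 rises and 2 falls adjusted over the list alone, and the Wnt antagonist DKK1 and the receptor FZD7 rose by 1.12 and 0.7 of 8 Wnt targets. The median of the Wnt list was -0.19 and its mean 0.07. COMP, a cartilage matrix protein, rose by 0.88 among 14 chondrogenic genes, and the phosphatase DUSP1 rose by 1.29 while EGR1 fell by 0.94 among 16 immediate early genes, with 1 rise and 4 falls adjusted over the list alone. The interferon-induced IFIT2 fell by 0.73, the only one of 23 interferon genes to pass, and TRIB3, PLK2 and JARID2 fell as the only members of the ER stress, p53 and polycomb lists, by 0.83, 0.63 and 0.9. The median and mean of the ER stress list (0.06 and -0.05) and of the stromal list (-0.03 and 0.11) differed in sign. ANKH rose by 0.56 in the bone matrix list, where TNFRSF11B fell, and the stromal markers MCAM and ENG rose by 1.46 and 0.58. The demethylase, contractile, cell cycle, cholesterol, hypoxia, blood, endothelial and muscle lists had 0 genes past limma's threshold. Of all genes tested, 2.1% passed it, so 0 in a short list says little, and 2104 had an unadjusted p under 0.05. KDM4B and KDM6B did not pass, at 0.05 and -0.50. Of 45 named calls, 22 held with every array and every arm left out, and those of HOXB6, HOXC9, DLX3, MSX1, CEBPA, CCL2, IFIT2 and EGR1 were among the others. The 278 calls became 81 with the mean over probe sets and 38 without a variance trend, and 173, 105, 120 and 120 without the scramble array at 0 h, the scramble array at 4 h, the KDM4B array at 4 h or the KDM6B-labelled array at 0 h.

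After 24 h against 0 h, FGFR3, a receptor that restrains cartilage growth, rose by 4.62 ± 0.58 (adjusted p = 0.000289) and SOST, the secreted inhibitor of bone formation sclerostin, by 4.43 ± 0.4 (adjusted p = 1.75e-05). The transcriptional regulators HEY1 and LMO2 rose by 3.49 ± 0.39 and 3.31 ± 0.19, and the signal transducer SMAD9 by 2.86 ± 0.18. The attractants CCL2 and CCL7 fell by 3.56 ± 0.23 and 3.13 ± 0.37, and TNFRSF11B fell by 1.95 ± 0.09. The antiviral genes CMPK2, MX1, RSAD2 and OAS1 fell by 2.91 ± 0.19, 2.6 ± 0.21, 2.52 ± 0.23 and 2.43 ± 0.21. In all, 423 genes rose and 432 fell.

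Of 23 interferon response genes, 22 fell at 24 h, 1 did not pass, and 23 fell adjusted over the list alone, with a median of -1.84 (camera adjusted p = 7.46e-44, adjusted p = 0.396 with an estimated correlation). The spiked RNAs also went from 14.88 to 14.51 in scramble, 15.7 to 15.44 in the KDM4B arm and 15.35 to 15.02 in the KDM6B-labelled arm on the log2 scale, and the ACTB 3' to 5' ratio from 6.42 to 5.55, 7.04 to 6.2 and 6.75 to 6.28. Of 21 NF-kB and inflammatory genes, 13 fell, 17 adjusted over the list alone, with a median of -1.17. Examples are CCL2, the cytokine IL1B at -2.77 ± 0.43 and the neutrophil attractant CXCL2 at -2.09 ± 0.36 (camera adjusted p = 1.03e-14, adjusted p = 0.592 with an estimated correlation). Without the KDM4B array at 0 h, the falls numbered 21 in the interferon list and 9 in the inflammatory list, and CXCL2 stood at -1.39. Of 16 BMP feedback targets, 11 rose and 0 fell, with 12 rises and 1 fall adjusted over the list alone, and their median was 2.14 (adjusted p = 0.0463 with an estimated correlation). All 5 DLX genes rose, also adjusted over the list alone, with DLX5, a driver of osteoblast differentiation, at 2.6 ± 0.22 (camera adjusted p = 4.51e-13, adjusted p = 0.158 with an estimated correlation). Of 19 HOX genes, HOXC6 alone rose, by 0.47 ± 0.12, with 1 adjusted over the list alone, and it did not pass under quantile normalization. The DLX and HOX lists again follow the published study and are not independent evidence. Of 13 osteogenic transcription factors, DLX3, DLX5, SP7, which is needed for osteoblast formation, and CBFB rose, by 2.84, 2.6, 2.67 and 0.99, with 6 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.00213, adjusted p = 0.43 with an estimated correlation). Of 7 Notch targets, HEY1, JAG1 and HES1 rose by 3.49, 1.63 and 1.55, also 3 adjusted over the list alone (camera adjusted p = 0.00328, adjusted p = 0.43 with an estimated correlation). Of 10 adipogenic genes, CEBPA and ZNF423 rose by 3.31 and 1.43, with 3 adjusted over the list alone (camera adjusted p = 0.0407, adjusted p = 0.592 with an estimated correlation), and PPARG stood at 1.14 (adjusted p = 0.0941). HOXC6 was chosen after its value was seen. Of 14 hypoxia and glycolysis genes, ADM and the glucose transporter SLC2A1 fell by 1.01 and 0.56, with 5 adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.724 with an estimated correlation).

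**Figure D2:**
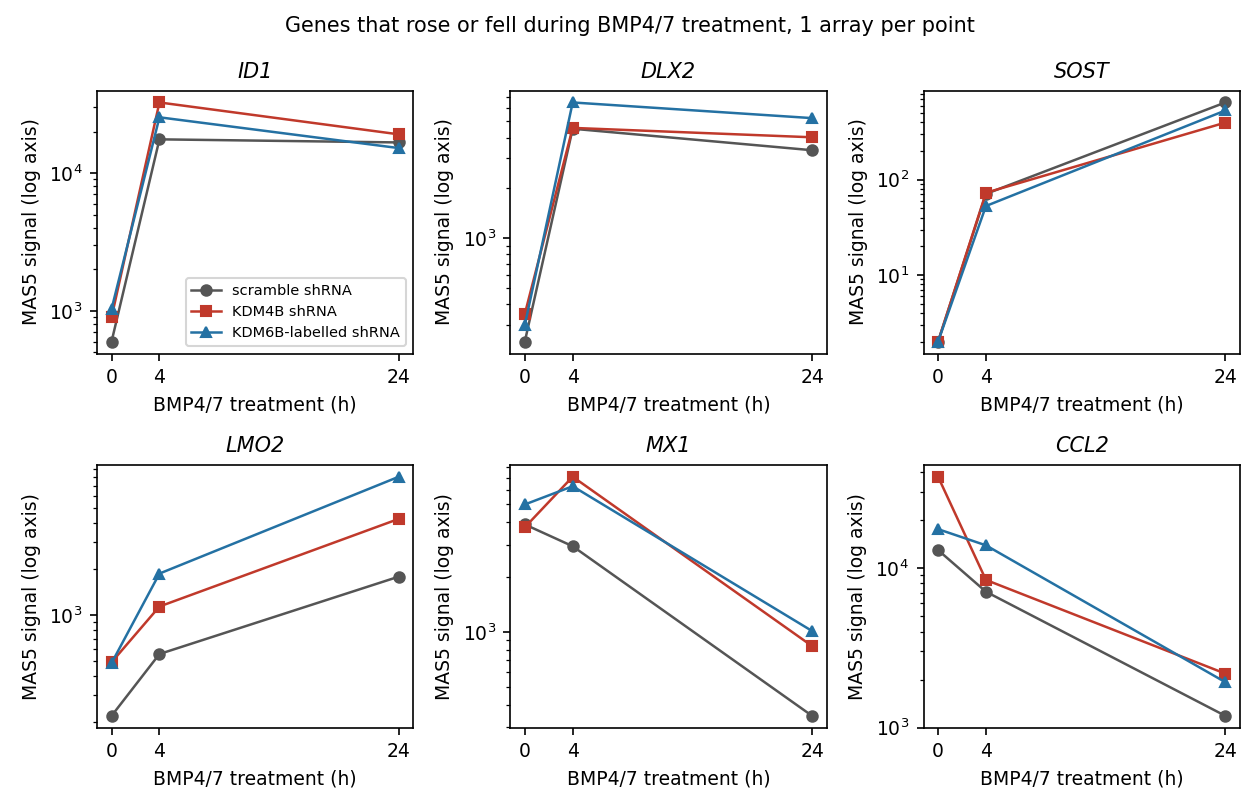
Signals of ID1, DLX2, SOST, LMO2, MX1 and CCL2 (vertical axes, MAS5 signal on a log scale) against hours of BMP4/7, with 1 array per point and 1 line per arm. On the log2 scale over the 3 arms, ID1 and DLX2 rose by 4.85 and 4.02 at 4 h, SOST and LMO2 rose by 4.43 and 3.31 at 24 h, and MX1 and CCL2 fell by 2.6 and 3.56 at 24 h.

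In the remaining lists at 24 h against 0 h, the cartilage genes COMP and ACAN rose by 1.38 and 2.58 of 14 chondrogenic genes, and the collagen cross-linking enzyme LOX and TPM1 rose by 0.58 and 0.38 of 18 contractile genes. ANKH rose by 0.93 and TNFRSF11B fell in the bone matrix list, whose median and mean were 0.07 and 0.05 while its test pointed down. DKK1 rose by 0.59 and CCN4 fell by 2.77 among the Wnt targets, with a median of 0.09 and a mean of -0.26. Of the immediate early genes, DUSP1 rose by 0.75 and IER3, JUN and ATF3 fell by 1.52, 0.98 and 1.82. ATF3 was also the only ER stress gene to fall, with 3 adjusted over the list alone, and it stood at -1.10 without the KDM4B array at 0 h. MCAM and ENG rose by 3.05 and 1.2, the endothelial marker PECAM1 fell by 1.72 with a list median of 0.03 and mean of -0.06, and TYMS fell by 0.63 as the only cell cycle gene. Only 1 of the 2 probe sets of MCAM rose. DUSP1 and TYMS were chosen after their values were seen. The p53, cholesterol, polycomb, blood, demethylase and muscle lists had 0 genes past limma's threshold. Of all genes tested, 6.5% passed it and 2352 had an unadjusted p under 0.05. Of 49 named calls, 39 held with every array and arm left out, and those of SP7, ACAN, ADM, SLC2A1, ATF3, DKK1 and TPM1 did not. The 855 calls became 477 with the mean over probe sets and 271 without a variance trend, and 534 or 560 without the KDM6B-labelled array at 0 h or at 24 h. No untreated array at 4 or 24 h was analysed here, so BMP and time in culture were not separated.

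Between 4 h and 24 h, ISM1, a secreted protein, rose by 2.81 ± 0.41 (adjusted p = 0.00125), SOST by 2.61 ± 0.4, DIO2, which activates thyroid hormone, by 2.33 ± 0.35, and FRZB, a secreted Wnt antagonist, by 2.24 ± 0.3. HEY1 rose by 1.99 ± 0.39, or 1.28 without the KDM6B-labelled array at 24 h, and JAG1 by 0.98 ± 0.1, while ID3 fell by 0.65, HES1 by 0.65 and CBFB by 0.68. CMPK2 and MX1 fell by 2.99 ± 0.19 and 2.88 ± 0.21, and CCL2 by 2.44 ± 0.23. In all, 469 genes rose and 525 fell.

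Of 23 interferon genes, 22 fell between 4 and 24 h, 23 adjusted over the list alone, with a median of -1.77 (camera adjusted p = 6.32e-40, adjusted p = 0.403 with an estimated correlation). The spiked RNAs were lower at 24 than at 4 h in every arm, and the ACTB ratio was lower in the KDM4B arm and higher in the others. Of 21 inflammatory genes, 8 fell, 14 adjusted over the list alone, with a median of -0.84 (camera adjusted p = 8.63e-09, adjusted p = 0.67 with an estimated correlation), and 15 fell without the KDM4B array at 0 h. Of 14 hypoxia and glycolysis genes, ANKRD37, SLC2A1 and PGK1 fell by 0.82, 0.5 and 0.37, also 3 adjusted over the list alone (camera adjusted p = 0.00624, adjusted p = 0.724 with an estimated correlation). Of 10 adipogenic genes, CEBPA and PPARG, the central regulators of fat cell formation, rose by 1.61 and 1.6, with 3 adjusted over the list alone. DKK1, FZD7 and CCN4 fell by 0.53, 0.5 and 2.38 among 8 Wnt targets, and TYMS and PCNA, genes of DNA synthesis, fell by 0.91 and 0.41 among 25 cell cycle genes. BAMBI, a decoy receptor for BMP, rose by 0.58 and PMEPA1 fell by 1.06 beside ID3 among the BMP feedback targets, whose median was 0.07 and mean -0.01. DLX6 rose by 0.98, the only one of the 5 DLX genes, while 0 HOX genes passed, and both lists follow the published study and are not independent evidence. The osteogenic factors RUNX2 and WWTR1 rose by 0.52 and 0.42, and that list's median of -0.05 and mean of 0.12 differed in sign, as did those of the Notch targets, -0.21 and 0.26. OMD and ANKH rose by 2.29 and 0.38 and TNFRSF11B fell by 1.07 in the bone matrix list. In the other lists, COMP rose by 0.5, LOX by 0.48, ZMAT3, a p53 target, by 0.38, EGR3 and EGR1 by 0.91 and 0.79, SLC7A11 by 0.82, JARID2 by 0.77 and MCAM, ENG and PDGFRA by 1.59, 0.62 and 0.58. MCAM and PDGFRA had 2 probe sets each, and only 1 of the 2 rose in each gene. JUN and DUSP1 fell by 0.86 and 0.54, DDIT4 by 0.92, the polycomb gene EED by 0.47, THY1 by 0.86 and PECAM1 by 1.79. The demethylase, cholesterol, blood and muscle lists had 0 genes past limma's threshold. Of all genes tested, 7.5% passed it and 2795 had an unadjusted p under 0.05. PDGFRA stood at 0.37 without the scramble array at 24 h, SLC7A11 at 0.50 without the scramble arm and 1.26 without the KDM6B-labelled arm, and EGR1 at 0.53 without the latter. PCNA, RUNX2, WWTR1, ANKH, COMP and DUSP1 were chosen after their values were seen. Of 53 named calls, 26 held with every array and arm left out, and those of CEBPA, PPARG, OMD, BAMBI, DLX6, HES1, DKK1, FZD7, ANKRD37, SLC2A1 and PGK1 did not. The 994 calls became 416 with the mean over probe sets and 142 without a variance trend, and 445, 516, 513 and 539 without the scramble array at 4 h, the KDM4B array at 4 h, the KDM4B array at 24 h or the KDM6B-labelled array at 4 h.

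Against scramble, the KDM4B arm had higher levels of NR4A2, an immediate early nuclear receptor, by 3.16 ± 0.52 (adjusted p = 0.00167), and of PTGS2, the enzyme of prostaglandin synthesis, by 2.87 ± 0.54 (adjusted p = 0.0039). Without the 0 h arrays they stood at 2.03 and 1.77 and still passed, and PTGS2 stood at 1.88 without the KDM4B array at 0 h alone. The steroid and aldehyde reductase AKR1C2 rose by 2.49 ± 0.18, and POSTN, a matrix protein, by 0.91 ± 0.08. The cartilage matrix genes COMP and COL11A1 fell by 1.91 ± 0.12 and 1.55 ± 0.15 (adjusted p = 7.41e-06 and 5.87e-05). The smooth muscle genes ACTA2 and CNN1 fell by 1.36 ± 0.15 and 1.44 ± 0.2, and the sterol synthesis enzyme MSMO1 by 1.88 ± 0.16. In all, 826 genes were higher and 773 lower in the KDM4B arm.

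Of 23 interferon genes, 15 rose in the KDM4B arm, 19 adjusted over the list alone, with a median of 0.63 and examples in OAS3 at 1.02 ± 0.16 and ISG15 at 1.03 ± 0.23. Camera's call (adjusted p = 3.37e-10) was lost, at an adjusted p = 0.663 with an estimated correlation. Of 21 NF-kB and inflammatory genes, 16 rose and VCAM1 fell, by 0.37, with 17 rises and 1 fall adjusted over the list alone and a median of 1.16. Examples are PTGS2, the attractant CXCL6 at 1.89 ± 0.36 and TNFAIP6, a secreted hyaluronan-binding protein, at 1.84 ± 0.23 (camera adjusted p = 7.62e-10, adjusted p = 0.663 with an estimated correlation). Without the 0 h arrays, 11 interferon and 8 inflammatory genes rose, and without the KDM4B array at 0 h alone 12 and 9. CXCL6 stood at 1.18 without that array, and ISG15 at 0.69 without the scramble array at 24 h. Of 14 hypoxia and glycolysis genes, 9 rose, also adjusted over the list alone, with the peptide hormone ADM at 1.17 ± 0.19 and the aldolase ALDOC at 0.92 ± 0.14 (camera adjusted p = 6.96e-06, adjusted p = 0.663 with an estimated correlation), and 4 rose without the 0 h arrays and 5 under quantile normalization. Of 13 cholesterol synthesis genes, 6 fell, 7 adjusted over the list alone, with INSIG1, a sensor of sterol level, at -1.35 ± 0.16 and SQLE at -1.29 ± 0.18 (camera adjusted p = 1.14e-05, adjusted p = 0.592 with an estimated correlation). Of 18 ER and amino acid stress genes, 8 fell and HSPA5 rose, by 0.34, with 10 falls and 3 rises adjusted over the list alone, and 4 fell without the 0 h arrays. Examples are ASNS, which makes asparagine, at -1.16 ± 0.12, TRIB3 at -1.11 ± 0.16 and PHGDH, which starts serine synthesis, at -0.83 ± 0.14 (camera adjusted p = 0.00143, adjusted p = 0.592 with an estimated correlation). The MHC class II genes CD74 and HLA-DRA, fixed as blood cell markers, rose by 0.99 ± 0.17 and 1.15 ± 0.31, 2 of 6 markers and also 2 adjusted over the list alone (camera adjusted p = 0.0228, adjusted p = 0.549 with an estimated correlation). The spiked control RNAs were 1.82-fold brighter in the same arm, and its ACTB 3' to 5' ratio was above that of scramble at every time.

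Of 14 chondrogenic genes, the transcription factor SOX5 rose by 1.28 and COMP, COL11A1, EPYC and HAPLN1 fell, EPYC by 2.54 and HAPLN1 by 0.89, with 5 falls adjusted over the list alone, a median of -0.01 and a mean of -0.42 (camera adjusted p = 0.0761). Of 18 contractile genes POSTN, TGFBI, FN1 and INHBA rose by 0.91, 0.77, 0.64 and 0.54 and 8 fell, with 5 rises and 8 falls adjusted over the list alone, but 1 rose and 12 fell under quantile normalization. COL1A1, COL1A2 and BMP2 rose by 0.41, 0.47 and 1.1 and COL5A2 fell by 0.39 of 14 bone matrix genes, 3 and 2 adjusted over the list alone, but under quantile normalization 0 rose and 2 fell and the median turned from 0.23 to -0.08. Of the BMP feedback targets, ID1, ID3 and GREM1 rose by 0.55, 0.46 and 0.6 and SKIL and SMURF2 fell by 0.93 and 0.48. FOSL2 rose by 0.56 and MSX1 and WWTR1 fell by 1.29 and 0.43 of 13 osteogenic factors, and CEBPA and G0S2 rose by 1.79 and 0.69 and CFD fell by 0.84 of 10 adipogenic genes. None of 5 DLX genes and none of 19 HOX genes passed, also adjusted over the list alone, with list medians of -0.15 and 0, and both lists follow the published study and are not independent evidence. Of 19 demethylases, KDM3A rose by 0.39 and KDM4B and KDM1B fell, KDM1B by 1.47, with a median of 0.03 and a mean of -0.04. The Notch receptor NOTCH3 rose by 0.7 and JAG1 fell by 0.84, and SFRP1 rose by 0.73 while DKK1 and FZD7 fell by 0.62 and 0.59, in a Wnt list whose median of 0.07 turned to -0.02 under quantile normalization and whose test pointed down. TYMS and PCNA rose by 0.91 and 0.66 and MCM6 fell by 0.6 of 25 cell cycle genes, whose median of 0.06 turned to -0.01 under quantile normalization. In the p53 list, GDF15, TNFRSF10B, CDKN1A and BAX rose by 0.81, 0.73, 0.64 and 0.64 and CDKN2B fell by 1.19, with 8 rises and 3 falls adjusted over the list alone. In the immediate early list, NR4A2, NR4A3, IER3 and DUSP1 rose by 3.16, 2.69, 1.59 and 0.53 and EGR1 and KLF6 fell by 0.9 and 0.66. JARID2 rose by 1.09 as the only polycomb component, in a list with a median of -0.05 and a mean of 0.03. Of the stromal markers, ENG, VIM, ITGB1 and CXCL12 rose by 0.63, 0.61, 0.47 and 0.4 and THY1, MCAM and ALCAM fell by 0.98, 0.58 and 0.57, but 1 rose and 2 fell under quantile normalization, where the median of 0.04 turned to -0.06. TEK fell by 1.17 among endothelial markers, and 0 of 2 muscle markers passed. BMP2 stood at 0.72 without the scramble array at 0 h, where CFD stood at -0.55, and at 0.60 without the KDM4B array at 0 h, where G0S2 stood at 0.36. MCAM stood at -0.38 without the scramble array at 24 h, and these 4 calls were then lost, while THY1 stood at -0.64 without all 0 h arrays and passed.

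HSPA5, VCAM1, HAPLN1, TGFBI, FN1, INHBA, COL1A1, COL1A2, COL5A2, ID3, SMURF2, WWTR1, KDM3A, PCNA, MCM6, CDKN1A, BAX, DUSP1, KLF6, ITGB1, CXCL12 and ALCAM in the KDM4B arm were chosen after their values were seen. DLX2 and DLX5 stood at 0.26 and -0.15 there and did not pass (adjusted p = 0.284 and 0.736). Of 75 named calls, 48 held with every array and every time left out, and those of PTGS2, NR4A2, COMP, COL11A1, ACTA2, INSIG1, ASNS and CD74 were among them, while those of NR4A3, KDM1B, HLA-DRA and BMP2 were not. The 1599 calls became 841 with the mean over probe sets and 387 without a variance trend, and 950, 750, 980 and 1006 without the scramble array at 0 h, the scramble array at 4 h, the KDM4B array at 0 h or the KDM4B array at 4 h.

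**Figure D3:**
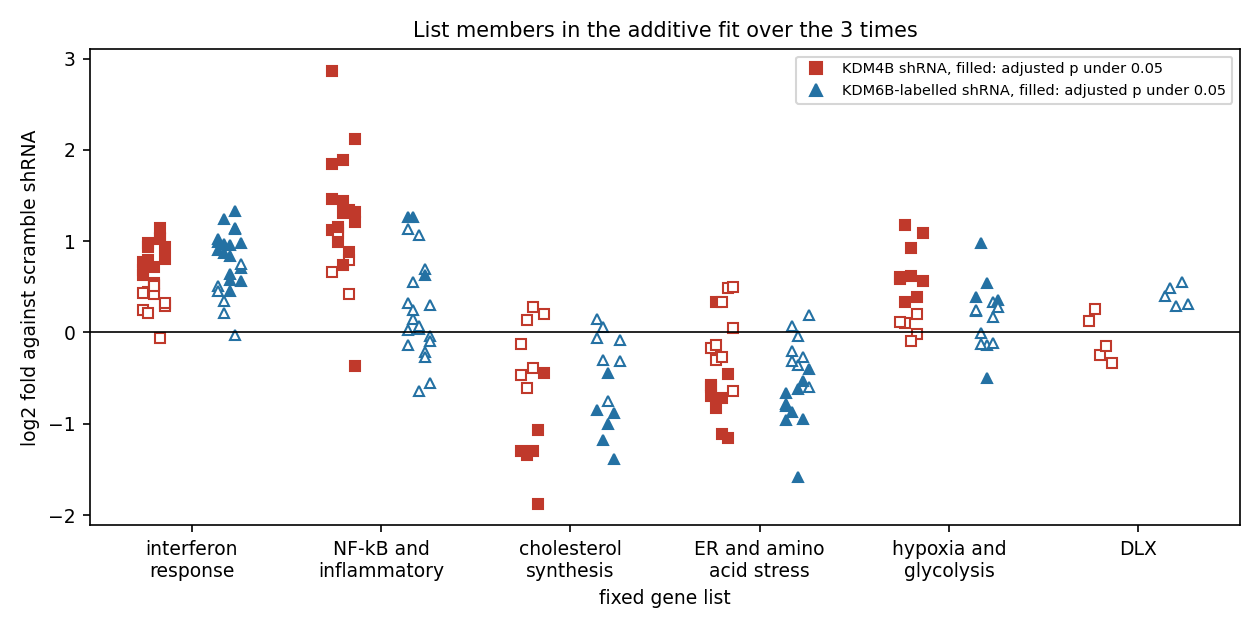
Log2 fold change against scramble (vertical axis) of the tested members of 6 lists (horizontal axis), with squares for the KDM4B arm, triangles for the KDM6B-labelled arm and filled marks for an adjusted p under 0.05. Of 23 interferon genes 15 and 17 rose, of 21 inflammatory genes 16 and 3 rose, of 13 cholesterol synthesis genes 6 and 6 fell, and of 5 DLX genes 0 and 0 passed.

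Against scramble, the KDM6B-labelled arm had higher levels of CP, the copper carrier ceruloplasmin, by 2.58 ± 0.38 (adjusted p = 0.00115) and of COLEC12, a scavenger receptor, by 2.44 ± 0.16. RARRES1, a retinoid-induced gene, rose by 2.27 ± 0.11 (adjusted p = 4.72e-07), and CFI, an inhibitor of complement, by 2.03 ± 0.13. KRT14, a keratin of basal epithelium, fell by 2.95 ± 0.23, COL11A1 by 2.13 ± 0.15 and COMP by 1.96 ± 0.12. In all, 659 genes were higher and 546 lower. The target KDM6B did not pass in this arm, so a direction here belongs to the arrays so labelled.

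Of 23 interferon genes, 17 rose in the KDM6B-labelled arm, 21 adjusted over the list alone, with a median of 0.84 and examples in OAS3 at 1.33 ± 0.16 and IFI44L at 1.25 ± 0.18 (camera adjusted p = 3.76e-14, adjusted p = 0.592 with an estimated correlation). At 0, 4 and 24 h the differences were 1.16, 1.08 and 1.76 for OAS3 and 0.82, 0.97 and 1.96 for IFI44L. ISG15 and IFI27 rose by 1.14 and 1.13. Without the 24 h arrays they stood at 0.66 and 0.58, and IFI27 then did not pass. Of 18 ER and amino acid stress genes, 10 fell and 0 rose, 13 adjusted over the list alone, with TRIB3 at -1.59 ± 0.16, DDIT3, a transcription factor of the stress response, at -0.96 ± 0.17 and ASNS at -0.94 ± 0.12 (camera adjusted p = 1.95e-10, adjusted p = 0.396 with an estimated correlation). Of 13 cholesterol synthesis genes, 6 fell, 7 adjusted over the list alone, with MSMO1 at -1.39 ± 0.16 and INSIG1 at -1.17 ± 0.16 (camera adjusted p = 2.14e-05, adjusted p = 0.592 with an estimated correlation). Of 14 chondrogenic genes, COMP, COL11A1, EPYC and HAPLN1 fell, EPYC by 2.04 and HAPLN1 by 0.99, also 4 adjusted over the list alone (camera adjusted p = 0.0204, adjusted p = 0.533 with an estimated correlation). CD74, HLA-DRA and HLA-DPA1 rose by 1.74 ± 0.17, 1.37 ± 0.31 and 2.08 ± 0.15, and CD74 and HLA-DRA were the 2 of 6 blood markers to pass, also adjusted over the list alone (camera adjusted p = 0.0228, adjusted p = 0.549 with an estimated correlation). Only 1 of the 2 probe sets of CD74 rose. The spiked control RNAs were 1.44-fold brighter in the same arm, and its ACTB 3' to 5' ratio was above that of scramble at every time. Of 21 inflammatory genes, TNFAIP6, the collagenase MMP1 and SOD2 rose by 1.26, 1.26 and 0.63, with 5 adjusted over the list alone, and 7 rose without the KDM4B array at 0 h. Of 14 hypoxia and glycolysis genes, ADM, ALDOC, PGK1 and LDHA rose by 0.98, 0.54, 0.39 and 0.36 and NDRG1 fell by 0.5, also 4 and 1 adjusted over the list alone, and 0 passed without the 0 h arrays.

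Of 14 bone matrix genes in the KDM6B-labelled arm, BMP2 and PTH1R rose by 1.12 and 0.84 and SPP1, ENPP1, TNFRSF11B and COL5A2 fell by 1.1, 0.95, 0.49 and 0.49, with a median of 0.05 and mean of -0.02, and under quantile normalization the median turned to -0.22 with 1 rise and 6 falls. ATOH8, GREM1, BAMBI and ID3 rose by 1, 0.83, 0.6 and 0.57 and SMURF2 and SKIL fell by 0.84 and 0.63 of 16 BMP feedback targets. FOSL2 rose by 0.42 and WWTR1 fell by 0.3 of 13 osteogenic factors, and CEBPA and ZNF423 rose by 1.65 and 1.12 and CFD fell by 0.84 of 10 adipogenic genes. Of 18 contractile genes POSTN, TGFBI, FN1 and TPM1 rose by 0.68, 0.51, 0.48 and 0.32 and CNN1, THBS1, ACTA2, MYL9 and LOX fell by 0.88, 0.74, 0.57, 0.51 and 0.43, with 5 rises and 7 falls adjusted over the list alone, and ACTA2 turned to 0.39 with the mean over its probe sets. SFRP1 and FZD7 rose by 0.62 and 0.4 of 8 Wnt targets, RRM2, TYMS and PCNA rose by 1.48, 0.69 and 0.49 and MCM6 fell by 0.51 of 25 cell cycle genes, and PLK2 and CDKN1B rose by 0.68 and 0.43 while CDKN2B and GDF15 fell by 1.17 and 0.47 in the p53 list. KLF4 and KLF6 fell by 0.89 and 0.58 among immediate early genes, with a median of -0.02 and a mean of 0.1. Of the stromal markers PDGFRA, CXCL12, ENG, ITGB1 and VIM rose by 0.61, 0.5, 0.49, 0.43 and 0.42 and THY1 fell by 0.71, but 2 rose under quantile normalization, where the median of 0.09 turned to -0.03, and TEK fell by 1.47 among endothelial markers, whose median was 0.19 while the test pointed down. The Notch, polycomb, muscle and demethylase lists had 0 genes past limma's threshold, and the demethylase median of 0.06 and mean of -0.03 differed in sign. Of all genes tested, 9.1% passed it and 2911 had an unadjusted p under 0.05. Without the scramble array at 0 h, BMP2 and CFD stood at 0.74 and -0.56 and did not pass. Nor did ATOH8 at 0.66 without the KDM6B-labelled array at 0 h, ACTA2 at -0.38 without that at 4 h, or SKIL at -0.41 and NDRG1 at -0.33 without that at 24 h. Of 5 DLX genes 0 passed and 1 did so adjusted over the list alone, with DLX2 at 0.49 (adjusted p = 0.0518), and 0 of 19 HOX genes passed either way, in lists that follow the published study and are not independent evidence.

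SOD2, LDHA, TNFRSF11B, COL5A2, TGFBI, FN1, TPM1, MYL9, LOX, ITGB1, VIM, BAMBI, ID3, FOSL2, WWTR1, FZD7, TYMS, PCNA, MCM6, CDKN1B, GDF15 and KLF6 in the KDM6B-labelled arm were chosen after their values were seen. Of 66 named calls, 33 held with every array and every time left out, and those of CP, COLEC12, RARRES1, CFI, KRT14, COMP and TRIB3 were among them, while those of HLA-DRA, EPYC, BMP2, CEBPA and RRM2 were not. The 1205 calls became 648 with the mean over probe sets and 83 without a variance trend, and 724, 598, 770 and 794 without the scramble array at 0 h, the scramble array at 4 h, the KDM6B-labelled array at 4 h or that at 24 h.

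Both arms shared many of these genes. FLG, the epidermal protein filaggrin, fell by 2.89 ± 0.34 in the KDM4B arm and by 3.18 ± 0.34 in the KDM6B-labelled arm, and the chemerin receptor CMKLR1 by 2.64 ± 0.52 and 3.01 ± 0.52. CP rose by 2.52 and 2.58, COLEC12 by 2.15 and 2.44, and COMP fell by 1.91 and 1.96. COLEC12 in the KDM4B arm was chosen after its value was seen. In all, 443 genes were higher and 296 lower in both arms, 739 together, and 4 went opposite ways. Independent lists of these sizes would share 41.1 higher and 31.9 lower genes, and the highest overlap in 100 simulated pairs of unchanged arms was 0. That 0 says nothing of the shared arrays, since unchanged arms gave at most 1 call in either comparison. Lists as long as the real ones, taken by p from the same simulations, shared a median of 423 and at most 469 genes that went the same way, a comparison chosen after seeing the data. Fold changes of the 2 arms correlated across genes with r of 0.64, where genes are not independent replicates, against 0.502 for simulated unchanged arms, and their covariance was 0.13 against 0.043, a difference of 0.087. The 3 scramble arrays are too few to split, so part or all of the excess over independent lists may come from the shared controls. The simulations hold random noise only and leave out any steady difference of the scramble arrays. Values above the simulated ones are therefore not free of the controls.

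Set directly against each other, the KDM4B arm exceeded the KDM6B-labelled arm in GDF15, a stress-induced cytokine, by 1.28 ± 0.13 (adjusted p = 0.00104) and in MMP3, a matrix-degrading enzyme, by 1.95 ± 0.33 (adjusted p = 0.0119), which was 1.22 and did not pass without the 0 h arrays. TNFRSF11B was higher by 0.71 ± 0.09 and SLC2A1 by 0.75 ± 0.13. The integrin ITGA8 fell by 1.53 ± 0.17, the Wnt receptor FZD7 by 0.99 ± 0.11 (adjusted p = 0.00104) and RUNX2, the master regulator of bone formation, by 0.66 ± 0.13. In all, 138 genes were higher and 140 lower in the KDM4B arm.

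Of 21 inflammatory genes, MMP3 and the attractant CCL20 were higher in the KDM4B arm than in the KDM6B-labelled arm, 18 with 1 fall adjusted over the list alone, with a median of 0.82 (camera adjusted p = 3.37e-10, adjusted p = 0.663 with an estimated correlation). Of 14 hypoxia genes, SLC2A1 and P4HA1 were higher, 7 with 1 fall adjusted over the list alone (camera adjusted p = 4.82e-05, adjusted p = 0.67 with an estimated correlation). Of 14 bone matrix genes, TNFRSF11B, SPP1 and ANKH were higher, also 3 adjusted over the list alone (camera adjusted p = 0.00365, adjusted p = 0.485 with an estimated correlation). Without the 0 h arrays, 0 genes of these 3 lists passed. VLDLR was higher by 0.64 as 1 of 18 ER stress genes, 5 adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.592 with an estimated correlation). None of 5 DLX genes passed and 2 were lower adjusted over the list alone, with a median of -0.54, in a list that follows the published study and is not independent evidence (camera adjusted p = 0.039, adjusted p = 0.619 with an estimated correlation). GDF15, TNFRSF10B and CDKN1A were higher in the p53 list, G0S2 was higher by 1.22 and ZNF423 lower at -0.80 in the adipogenic list, and KLF4 was higher by 0.68, chosen after its value was seen. BAMBI, RUNX2, ACTA2, JAG1, FZD7, ALCAM and CD74 were the only members of their lists to fall, at -0.55, -0.66, -0.79, -0.61, -0.99, -0.56 and -0.75. Only 1 of the 2 probe sets of CD74 was lower. The interferon, cholesterol, chondrogenic, cell cycle, HOX, polycomb, demethylase, endothelial and muscle lists had 0 genes past limma's threshold. Of all genes tested, 2.1% passed it and 2262 had an unadjusted p under 0.05. The median and mean differed in sign for the demethylases (0.07 and -0.01) and the blood markers (-0.06 and 0.02). Of 38 named calls, those of FZD7, GDF15 and ITGA8 alone held with every array and every time left out. The 278 calls became 52 with the mean over probe sets and 0 without a variance trend. With single arrays left out they ranged from 39 without the KDM6B-labelled array at 0 h to 383 without the scramble array at 24 h. They were 151 without the scramble array at 4 h, 140, 96 and 64 without the KDM4B arrays at 0, 4 and 24 h, 103 without the KDM6B-labelled array at 24 h, and 21 without all 0 h arrays.

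Whether the response to BMP differed between an shRNA arm and scramble was asked with the interaction model. In the KDM4B arm, the change of the cytokine IL11 differed from that in scramble by -3.71 ± 0.31 (adjusted p = 0.00604), and that of ID2 by -1.94 ± 0.18 (adjusted p = 0.00772). IL11 fell in the KDM4B arm, from 12158 at 0 h to at most 1568 later. ID2 rose by less, by 1.68 at 4 h against 3.54 in scramble. The baseline of this comparison is 1 array per arm at 0 h, which the model fits exactly. Its errors therefore come from the 4 and 24 h arrays alone, and the p-values cannot weigh how far a single 0 h array lies from its arm's usual level. IL11 had a signal of 12158 in the KDM4B array at 0 h and of 480 to 1568 in the other 8 arrays, and ID2 had 12444 there against 2532 and 3130 in the other arrays at 0 h. NR4A2, CXCL3 and PTGS2 stood at -3.40, -2.22 and -3.28 and did not pass (adjusted p = 0.0896, 0.106 and 0.366). Both calls were lost with the mean over probe sets and without a variance trend, each with 0 genes. limma called 0 genes with a positive difference, and 845 genes had an unadjusted p under 0.05, where 662 are expected by chance.

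Of 21 inflammatory genes, IL11 alone passed in the KDM4B arm's response, 16 were lower adjusted over the list alone, and all 21 were negative with a median of -1.39 (camera adjusted p = 4.44e-28, adjusted p = 0.592 with an estimated correlation). Fry called 0 lists in the KDM4B arm's response. No gene passed in the immediate early list (0 and 4 rose and fell adjusted over the list alone, median -0.38), the interferon list (1 and 0, median 0.46), the contractile list (8 and 1, median 0.39) or the bone matrix list (0 and 0, median -0.41). Camera called these 4 lists at an adjusted p of 0.000132, 1.48e-05, 0.00264 and 0.0216, and the values were adjusted p = 0.592, 0.724, 0.724 and 0.619 with an estimated correlation. ID2 was the only one of 16 BMP feedback targets to pass. The median and mean differed in sign, or from the test, for the osteogenic (0.15 and 0.07, test down), chondrogenic (-0.01 and -0.17, test up) and polycomb (0.01 and 0.17, test down) lists. In the KDM6B-labelled arm, limma called 0 genes, with 557 at an unadjusted p under 0.05 and a smallest adjusted p of 0.992. The interferon list alone was called there, with 0 genes past the threshold, also adjusted over the list alone, a median of 0.41 and camera's adjusted p at 9.08e-06 (adjusted p = 0.724 with an estimated correlation). There the median and mean differed in sign for the contractile (-0.09 and 0.02), p53 (-0.1 and 0.02) and blood (-0.19 and 0.11) lists. The model could not be fitted without the 0 h array of scramble or of the arm compared, and the 2 calls became 65 and 64 without the KDM6B-labelled arrays at 4 and 24 h, 32 and 6 without the scramble arrays at 4 and 24 h, and 7 and 14 without the KDM4B arrays at 4 and 24 h. The count of 0 became 19 without the KDM6B-labelled array at 4 h.

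**Figure D4:**
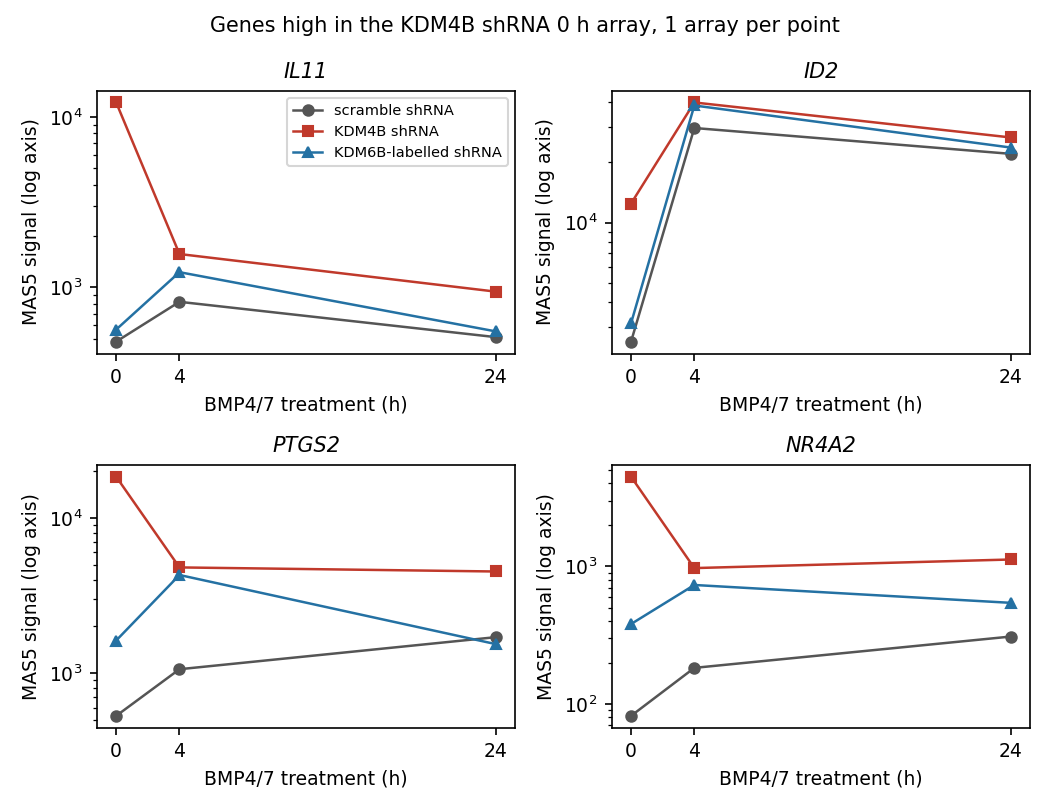
Signals of IL11, ID2, PTGS2 and NR4A2 (vertical axes, MAS5 signal on a log scale) against hours of BMP4/7, with 1 array per point and 1 line per arm. At 0 h the KDM4B array had 12158 for IL11, 12444 for ID2, 18404 for PTGS2 and 4476 for NR4A2, against 480, 2532, 532 and 81.7 in the scramble array.

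The size of the BMP response over genes such as ID1, DLX2 and SOST was compared between arms by regressing each arm's fold changes on the mean of the 3 arms. Over the 278 genes called at 4 h, the slopes were 1.02 for scramble, 0.985 for the KDM4B arm and 0.999 for the KDM6B-labelled arm. Over the 855 genes called at 24 h, they were 0.983, 0.968 and 1.05. The 3 slopes average 1 by construction, and the additive model favours genes whose change was alike in the arms, so close slopes were selected for. These are values without a test, since genes are not replicates, and they do not show that the arms responded alike. With genes chosen by a 2-fold rise in 1 arm, that arm's slope was the highest in each case, from 1.2 to 1.49.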

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

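The tests of blood cells, of noise in the shared scramble arrays, of the level after BMP and of the 0 h array were chosen only after the result was seen, and that of the hybridisation controls after the data but before its own result was seen, while that of other splits of the arrays was fixed earlier.

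The first pattern is the set of genes changed the same way in both shRNA arms against scramble, beside spiked hybridisation controls that lay above the scramble level by 1.818-fold in the KDM4B arm and 1.437-fold in the KDM6B-labelled arm, with SDs of 0.146 and 0.162 on the log2 scale over 3 arrays, and an ACTB 3' to 5' ratio that was higher in both arms at every time (6.2 to 7.04 against 5.03 to 6.42). With the control level as a covariate the median shift of these genes went from 0.69 to 0.78, a share of 1.13 kept with a range of 0.55 to 1.75 over arrays left out, but arm and time set 99.2% of the control level (variance inflation 122, unscaled error 9.53 times larger), so that control level and arm cannot be told apart; the limit of 10 on the inflation, which voids this test although its bound of 0.5 was met, was set after the 122 was seen. The 739 shared genes cannot be set against the overlap of 0 in simulated unchanged arms, which give almost no calls, and simulated lists as long shared up to 469, so noise of the scramble arrays may account for part of them. The simulations leave out any steady difference of the scramble arrays, which could account for more of the shared genes or for all. Blood cells in the shRNA arms could raise CD74 and HLA-DRA, and of 9 markers outside MHC class II 3 were tested, with a median of 0.68 over both arms (CD14 1.17 and 0.32, ITGAM 0.38 and 0.58, CD34 0.86 and 0.5) and 0 past the threshold in both arms, too few to decide. These 3 markers were also dim, so a difference in background can enter their folds. Their scramble means were 5.64, 6.39 and 6.65 on the log2 scale, where the medians of tested genes in the scramble arrays were 9.17 to 9.23. RNA integrity and an effect of the shRNAs on the cells stay open and were not tested apart from these.

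The second pattern is a more negative BMP response in the KDM4B arm, where IL11 differed from scramble by -3.71 and ID2 by -1.94 in the interaction model and the 21 inflammatory genes had a median of -1.39. For inflammatory genes such as CXCL2 and IL1B this was a larger fall. They changed by -3.55 and -4.26 at 24 h in the KDM4B arm, against -1.37 and -1.74 in scramble. For ID2 it was a smaller rise at 4 h. A level below that of scramble after BMP is argued against. The lower of the arm's medians at 4 and 24 h was 0.63 above scramble. Without the 0 h arrays 8 of 21 genes rose and 0 fell, a further condition added after the values were seen. These values follow from the arm's difference from scramble and the interaction together, so they are no separate test of the BMP response. The arm stood above scramble at every time, so they cannot show whether BMP itself lowered these genes by more. The list's excess over scramble was 2.18 at 0 h, 0.89 at 4 h and 0.63 at 24 h, against 0.08, 0.8 and -0.15 in the KDM6B-labelled arm, but the drop of 1.29 is the negative interaction in another form and cannot test whether a high level in the 0 h array accounts for it. The excess at 0 h rests on 1 array, which the model fits exactly and whose spread the p-values leave out, and which also had the highest ACTB 3' to 5' ratio, 7.04. Whether it belongs to the untreated state of KDM4B-depleted cells or to the handling of 1 culture was not tested.

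The arrays of 2 groups can be split in 10 ways, the real one included and without regard to the time or arm they share, for each of the 6 additive comparisons, too few for a share under 0.05. The real split gave 1599, 1205, 278, 278, 855 and 994 genes for KDM4B against scramble, KDM6B-labelled against scramble, KDM4B against KDM6B-labelled, 4 h against 0 h, 24 h against 0 h and 24 h against 4 h. The highest other split gave 0, 0, 2, 0, 0 and 0, and 1 of the 10 splits, the real one, gave as many in each. Every other split mixes arms or times within a group, so a real difference between them counts as spread there. Low counts in those splits are built in and are no support for the real split. For the BMP response, the 6 splits that could be fitted are also too few. The real value was 2 genes for the KDM4B arm, reached by 2 of 6 splits, with a highest other of 1425, and 0 genes for the KDM6B-labelled arm, reached by 6 of 6 splits, with a highest other of 946. Both larger counts came from the split that exchanged the 0 h arrays of the arms, where the product of arm and treatment takes up the difference between the arms themselves.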

How the results depend on the processing

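The hybridisation controls as a covariate, list counts without some arrays, and further fits and left-out times for the levels of KDM4B and KDM6B were chosen after seeing the data. Over 332 gene results under 7441 alternative values, 99.5% kept their direction and 79.9% their direction and side of the threshold. Nearly all of these results were chosen because they had passed, and most called genes had 1 sign at every time or in every arm. Leaving out arrays, times or arms, which gave 3974 of the values, could then hardly turn a sign. The 99.5% is thus largely built in and is no sign of stability. The additive model pairs the arms by time and the times by arm; no paired analysis was possible by replicate number because each arm and time has 1 array. Quantile normalization and median centring moved no median of all genes by over 0.1 and no share of higher calls by over 10 points. The arrays' signal over background limits dim genes, since an array had 47.1 to 53.2% of its probe sets above 81.86. The cause was not tested for any change below, except that fewer arrays leave fewer degrees of freedom.

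With the mean over probe sets the counts were 841 for KDM4B against scramble, 648 for KDM6B-labelled against scramble, 52 between these arms, 81 at 4 h against 0 h, 477 at 24 h against 0 h, 416 at 24 h against 4 h and 0 for the KDM4B arm's response, with KDM4B at -0.277 (adjusted p = 0.339, against 0.00172), KDM6B at -0.234 (adjusted p = 0.619), ACTA2 at 0.392 in the KDM6B-labelled arm and slopes at 4 h of 1.006 (KDM4B) and 0.981 (KDM6B-labelled). The share of higher calls was 85.2% there against 60.1% at 4 h, 61.5% against 49.6% between the shRNA arms and 38% against 47.2% at 24 h against 4 h. Without a variance trend the counts were 387, 83, 0, 38, 271, 142 and 0 in the same order, with KDM4B at -0.771 (adjusted p = 0.0532). The KDM4B arm's response gave 5 genes with 4 times the added constant, 5 with a robust trend and 0 with the product with 24 h only. With only the arrays of the groups compared, 166 genes differed between the shRNA arms and 424 at 4 h against 0 h. With an estimated correlation 2 list calls held of 38. The slopes at 4 h were 1.032 (scramble) and 0.967 (KDM4B) under median centring and 1.033 and 0.967 with an added constant of 1.

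With genes that rose 2-fold in 1 arm, the slopes of scramble, KDM4B and KDM6B-labelled were 1.328, 0.78 and 0.892 at 4 h and 1.196, 0.839 and 0.965 at 24 h for scramble's genes, 0.744, 1.485 and 0.772 and then 0.786, 1.304 and 0.909 for the KDM4B arm's, and 0.868, 0.771 and 1.361 and then 0.831, 0.845 and 1.324 for the KDM6B-labelled arm's. That choice favours the arm it is made in by construction.

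With the hybridisation controls as a covariate, a void setting because arm and time set nearly all of their level, the counts were 0, 0 and 0 for the comparisons of arms and KDM4B stood at -0.989 (adjusted p = 1). Genes whose sign turned there in KDM4B against scramble were NOTCH3 -2.305, TAGLN 0.199, POSTN -0.203, FZD7 0.611, CEBPA -3.006, TYMS -0.162, SOX5 -2.525, ENO2 -0.134, ALDOC -1.467, IER3 -0.805, EGR1 0.583, OAS1 -0.32, EPYC 0.934, C11orf96 -1.281, MSX1 1.176, TNFRSF10B -0.111, VIM -0.269, MCAM 1.861, DLX2 -0.382 and DLX5 1.662. In KDM6B-labelled against scramble they were CEBPA -1.261, ENPP1 0.158, ALDOC -0.903, PRL 0.802, EPYC 0.065, LBP -1.495 and CLSTN2 -1.644, and between the shRNA arms VLDLR -0.1, P4HA1 -0.015, CYP27A1 0.169, TCEAL7 0.649, TPCN1 -0.494 and GPRC5A -0.576. DLX5 in KDM4B against scramble, which had not passed, ranged from -0.327 without the KDM4B array at 4 h to 0.119 without that at 0 h, and stood at 0.07 without the 0 h arrays.

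With single arrays, times or arms left out, the counts ranged from 692 to 1770 for KDM4B against scramble, 485 to 1343 for KDM6B-labelled against scramble, 21 to 383 between the shRNA arms, 104 to 395 at 4 h against 0 h, 518 to 823 at 24 h against 0 h and 417 to 1130 at 24 h against 4 h. The lowest came without the 4 h arrays for the first and second, the 0 h arrays for the third, the scramble arm for 4 h against 0 h and 24 h against 4 h, and the KDM6B-labelled arm for 24 h against 0 h. Counts without the 0 h arrays were 740 and 705 for the KDM4B and KDM6B-labelled arms against scramble, and without the 4 h or 24 h arrays 104 and 111 between the shRNA arms. Without the KDM4B and KDM6B-labelled arms in turn they were 128 and 164 at 4 h against 0 h and 493 and 628 at 24 h against 4 h, and 526 without scramble at 24 h against 0 h. The response counts ranged from 2 to 65 for the KDM4B arm and 0 to 19 for the KDM6B-labelled arm, and 7 of 9 arrays could be left out. KDM4B ranged from -0.918 to -0.654 and passed in 12 of 12 cases, and KDM6B from 0.186 to 0.38. The slopes ranged at 4 h from 1.014 to 1.028 (scramble), 0.969 to 0.978 (KDM4B) and 0.995 to 1.017 (KDM6B-labelled), and at 24 h from 0.976 to 0.989, 0.96 to 0.973 and 1.048 to 1.051.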

Other observations

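For interferon genes, tests of a larger fall from a higher start and of signs of array quality were chosen after the result was seen. That of array scaling was fixed earlier.

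KRT14, KRT16 and FLG, which are genes of keratinised epithelium, lay lower in both shRNA arms. KRT14 fell by 2.06 ± 0.23 in the KDM4B arm and by 2.95 ± 0.23 in the KDM6B-labelled arm, KRT16 by 1.98 ± 0.28 and 2.51 ± 0.28, and FLG by 2.89 and 3.18 (adjusted p from 2.19e-05 to 0.000602). The aldehyde and steroid reductases AKR1C1 and AKR1B10 were higher in both arms, AKR1C1 at 2.33 ± 0.19 and 1.4 ± 0.19 and AKR1B10 at 1.99 ± 0.17 and 1.49 ± 0.17. HGF, a growth factor secreted by stromal cells, rose by 1.4 ± 0.2 and 1.76 ± 0.2, and the acute phase protein LBP rose by 2.45 ± 0.49 in the KDM6B-labelled arm. The matrix genes MXRA5, COL15A1 and COL8A2 fell by 1.98, 1.9 and 1.53 in the KDM4B arm and by 1.85, 1.59 and 1.47 in the KDM6B-labelled arm. AKR1B10, HGF, MXRA5, COL15A1 and COL8A2, KRT16 in the KDM4B arm, AKR1C1 in the KDM6B-labelled arm and the grouping of these genes were chosen after their values were seen, no list of them was tested, and both arms share the scramble arrays.

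The third pattern is the lower level of interferon genes at 24 h in every arm, in 22 of 23 genes over the 3 arms. Array scaling is argued against as its cause, since at least 22 of the genes passed under quantile normalization and median centring. So are RNA integrity as read from the ACTB ratio and hybridisation as read from the spiked controls, each as the whole cause. The spiked RNAs entered at the hybridisation and do not show the labelling of the samples, which stays open. The ACTB ratio and the spiked controls were lower at 24 h than at 0 h in every arm. At least 0.92 and 0.45 of their falls were there at 4 h, against at most 0.06 of the list's fall. The list medians at 4 h were -0.13, 0.22 and 0.01 in scramble, the KDM4B arm and the KDM6B-labelled arm. Median changes to 24 h were -2.17, -1.66 and -1.45 in these arms, from medians of 11.02, 11.22 and 11.45 on the log2 scale. If a higher start meant a larger log2 fall, the shRNA arms would fall by more, and they fell by less, by 0.51 and by 0.71. A fall by the same share of the signal would give equal log2 changes and was not weighed. The list's interaction was not called by camera with an estimated correlation (adjusted p = 0.724 in both arms), a condition added after the values were seen. A larger fall from a higher start thus stays open. BMP and time in culture may both contribute, and no untreated array at 24 h was analysed here to separate them.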
